A study of Mus musculus with 20 samples.

How the data were processed

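The samples were B220-enriched cells from normal spleen (n = 4) and from VavPBcl2 lymphomas with an empty vector (n = 8) or with Myc (n = 8), of the C57BL/6 background, per the labels. Poly-adenylated RNA was sequenced on Ion Proton instruments, per the labels' protocols. The table holds counts per Ensembl gene of the mouse; the submitters' processing notes name BWA 0.7.5a, Picard 1.119, HTSeq and the builds mm9 and NCBIM37, with no role or order for each. The deposited values are raw counts per gene, with 1 column per sample, and the authors applied no scaling that the labels record. The table holds 37620 genes, of which 25632 have a count in any sample, and 5 further lines for reads assigned to no gene. Gene names came from GENCODE vM21, used for names only: 32897 identifiers matched a name and 4723 did not. Reads aligned to more than 1 place have a line of their own beside the gene counts, so families of near-identical genes (ribosomal proteins, Hba-a1 and Hba-a2, Hspa1a and Hspa1b, and the Klra, Klk1b, Stfa and trypsin families) may have lost or split reads.

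Per sample, 55.3 to 105.1 M reads (M for 1e6) were listed, and 37.1 to 57.0% of them (median 52.0%) were counted to genes. Of all reads, 14.3 to 40.3% were aligned to more than 1 place, 8.3 to 24.0% lay outside genes and 1.0 to 16.4% were not aligned; these stayed out of library sizes and tests. The 10 largest genes held 4.3 to 21.6% of the gene counts. The common biological coefficient of variation between samples of a group was 0.47.

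Groups, comparisons, tests, gene lists, named-gene rule and alternatives were written down before the data were examined. The run order was read from run numbers per instrument and title prefixes (4 instruments, 6 prefixes), with 7 samples in the later runs and 13 in the earlier. Because no Myc lymphoma and only 1 normal sample came from the later runs, run and group overlap, and each comparison was repeated within the earlier runs and with a run term.

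Genes were filtered with filterByExpr by group (17824 kept), scaled by TMM and tested with edgeR 4.0.16's quasi-likelihood F test (two-sided) in a single fit of 20 samples and 3 groups; Benjamini-Hochberg adjusted p under 0.05 was called. Log2 fold changes carry standard errors (SE). CPM are computed from TMM-scaled library sizes, and log2 CPM use a prior count of 2. Lists were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01, adjusted over 40 lists, and again with a correlation estimated per list. The 40 lists name 757 members (741 distinct), of which 10 were not found by name (Rpl24, Cdkn2d, Bcl2a1a, Bcl2a1d, Hmgcs1, Ighd, Psmb9, Hbb-b1, Ahsp and Ccl21a). Counts of members that rose or fell are given from the test over all genes and adjusted over the list alone. No overlap means that all samples of a group lie above all samples of the other.

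The lists are ribosome biogenesis, cytosolic ribosomal proteins, translation factors and tRNA synthetases, nucleotide synthesis, serine and one-carbon metabolism, glycolysis, mitochondrial translation and import, oxidative phosphorylation, amino acid uptake and polyamine synthesis, DNA replication, mitosis, G1 cyclins, kinases and inhibitors, Myc and its dimerisation network, Bcl2 family, p53 targets, unfolded protein and amino acid response, and cholesterol synthesis. For B cells, signalling and immunity they are pan-B-cell, mature follicular, marginal zone and B-1, germinal centre, plasma, pro-B and pre-B, NF-kB targets, MHC class II, MHC class I presentation, interferon response, and genes recurrently mutated in B cell lymphoma. For other cells and sample handling they are T cell, activated and follicular helper T cell, NK and cytotoxic, plasmacytoid dendritic, conventional dendritic, macrophage and monocyte, neutrophil, erythroid, megakaryocyte and platelet, stromal and endothelial, immediate-early and dissociation response, and mitochondrially encoded.

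The named genes are Myc and Bcl2; for each comparison the 10 genes that rose and the 10 that fell furthest among those called, with at least 5 CPM in the higher group and no overlap, leaving out immunoglobulin and T cell receptor segments, genes without a symbol, Xist and genes of the Y chromosome; the 2 to 4 list members with the smallest p of each described list; and the fixed genes Ptprc, Cd79a, Bcl6, Cdkn1a, Cdkn2a, Trp53, Odc1, Ldha, Shmt2, Ncl, Sesn1 and Tnfrsf14. Some genes that the rule names are not reported here. Where a group held 0 to 3 counts of a gene, CPM are given and no fold change.

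Immunoglobulin measures were the share of V gene counts held by the largest heavy (27 genes in the table) or kappa (59 genes) V gene, the share of switched isotypes among heavy constant counts (6 genes) and the lambda share of light chain constant counts (1 lambda gene), for samples with at least 200 counts. Groups were compared by exact two-sided permutation of the difference in means, adjusted over 12 tests, and shares of single samples carry 95% exact Clopper-Pearson intervals. Igha and Ighd were not used here. Correlations used exact permutation of the pairing of the values.

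The edgeR steps were tested on data simulated with each comparison's group sizes. Planted changes of 1.5-, 2- and 4-fold were called for 6, 31.3 and 72.7% of genes for Myc against vector, 6, 22.4 and 63.6% for vector against normal and 1.5, 16.4 and 56.1% for Myc against normal, with 4, 2 and 0 false calls. A planted list (oxidative phosphorylation, 1.5-fold) ranked 1 in all 3. Of 39 other lists 1, 0 and 1 were called, but random splits of real samples called medians of 15, 16 and 17. No duplicates were found (lowest chi-square per gene within a group 50.5, far above 1).

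Alternatives tried were RLE and upper-quartile factors, immunoglobulin genes left out, no low-count filter, DESeq2 1.42.0, limma-voom with and without sample weights, only the compared groups in the fit, instrument or later run as covariate, only the earlier runs, correlation within title prefix, a replicate number block, stricter thresholds, and leaving out each replicate or title prefix. Added after seeing the data were covariates for the erythroid, neutrophil and immediate-early lists and for the share of reads aligned to more than 1 place, autosomal genes only, and fry for lists. A result is called reversed only where it or its alternative is called or, for a value without a call, where its sign changes. Computation used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Positions in the genome, sequence variants and V-D-J rearrangements were not analysed here, because only counts per gene were used.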

Results

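Messenger RNA was sequenced from mouse cells enriched with magnetic beads for B220, the form of the CD45 surface protein found on B cells. The mice were of the C57BL/6 background. 4 samples came from normal spleen. 8 samples came from lymphomas of the VavPBcl2 model transduced with an empty vector, and 8 from lymphomas of the same model transduced with Myc. VavPBcl2 mice carry a transgene for Bcl2, a protein that blocks apoptosis, expressed in blood cells. Myc is a transcription factor that promotes cell growth and division. Nothing in the labels says that the replicates of a group came from separate animals, so the p-values measure the spread between these samples. Each sample held 28.7 to 56.3 M counts (M for 1e6) assigned to genes (43.0 to 52.95 M in normal samples, 28.7 to 56.3 M in vector lymphomas, 33.5 to 45.7 M in Myc lymphomas), and 17824 genes were tested.

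The 3 groups separated over the first 2 principal components of log2 CPM (counts scaled to a library of 1e6). PC1 held 38.3% of the variance and ran from -88.6 to -18.2 in vector lymphomas, from -83.8 to -28.3 in normal samples and from 60.3 to 190.9 in Myc lymphomas. Myc replicate 5 stood apart at 190.9, while the next Myc lymphoma lay at 97.1. The median Spearman correlation across genes between samples was 0.985 within normal samples, 0.974 within vector lymphomas and 0.961 within Myc lymphomas. Between groups it was 0.95 for vector and normal samples, 0.925 for Myc and vector lymphomas, and 0.922 for Myc lymphomas and normal samples. Going by the run numbers on each instrument, normal replicate 1 and vector replicates 1 to 6 (7 samples) came from later sequencing runs and the other 13 samples, all 8 Myc lymphomas among them, from earlier runs. Within the earlier runs 8 Myc lymphomas can be set against vector replicates 7 and 8 and normal replicates 2 to 4. Lists are given with their values there, or with whether the call held, and named genes that lost their call there are told for each comparison. Vector replicates 7 and 8 share a title prefix found in no other sample, so run and prefix coincide within the vector lymphomas. Both of the Y chromosome genes Ddx3y and Eif2s3y reached 5 CPM in 0 of 4 normal, 6 of 8 vector and 5 of 8 Myc samples, so sex is not balanced between the groups, and its effect was not tested.

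**Figure D1:**
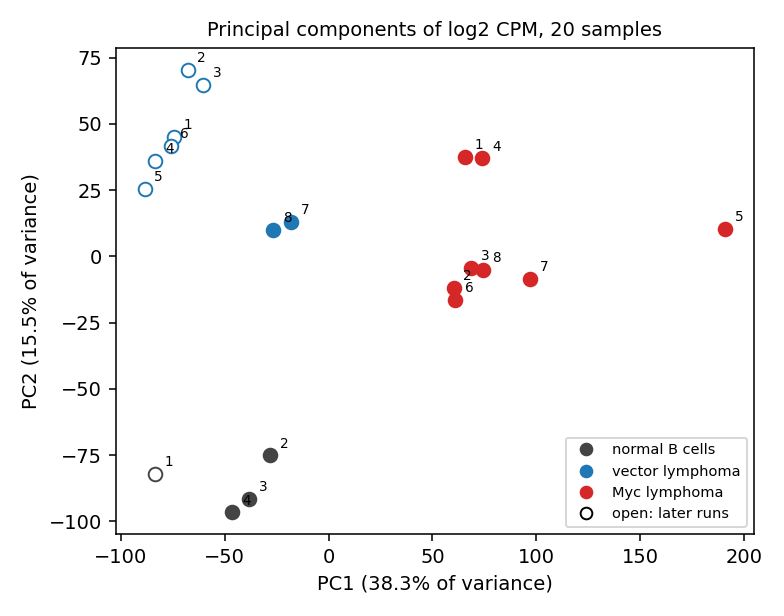
Principal components of log2 CPM for the 20 samples, with PC1 (38.3% of the variance) on the horizontal axis and PC2 (15.5%) on the vertical axis; each point is 1 sample, numbered by replicate and coloured by group, and open points are the 7 samples of the later runs. The 8 Myc lymphomas lie at PC1 values of 60.3 and above, and every vector lymphoma and normal sample lies below -18.

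Myc transcript (ENSMUSG00000022346) was measured in every sample. The vector lymphomas held 73, 186, 69.1, 128, 226, 61.4, 48.3 and 153 CPM for replicates 1 to 8, a mean of 118 ± 65.6 CPM (SD, n = 8). The Myc lymphomas held 962, 856, 820, 717, 313, 1650, 1180 and 1340 CPM, a mean of 979 ± 409 CPM (SD, n = 8), and each of them lay above every other sample except normal replicate 4. Normal B cells held 229, 218, 179 and 343 CPM, a mean of 242 ± 70.8 CPM (SD, n = 4), and normal replicate 4 lay above Myc replicate 5. Myc was 8.29-fold higher in Myc than in vector lymphomas (log2 fold change 3.05 ± 0.35 SE, adjusted p = 1.2e-06) and 3.29 on the log2 scale within the earlier runs (adjusted p = 0.008). Against normal B cells it was 4.04-fold higher in Myc lymphomas (2.01 ± 0.44, adjusted p = 0.0015, 2.02 and 0.013 within the earlier runs). The vector lymphomas did not differ from normal B cells at the threshold (-1.04 ± 0.39, adjusted p = 0.095, -1.27 and 0.57 within the earlier runs). Counts at Bcl2 (ENSMUSG00000057329) were alike in the 3 groups, at 126 ± 9.19 CPM in normal B cells, 122 ± 20.1 in vector lymphomas and 120 ± 43.2 in Myc lymphomas (adjusted p = 0.79 to 0.92 in the 3 comparisons). How reads of the Bcl2 transgene were counted is not given in the sources used here.

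**Figure D2:**
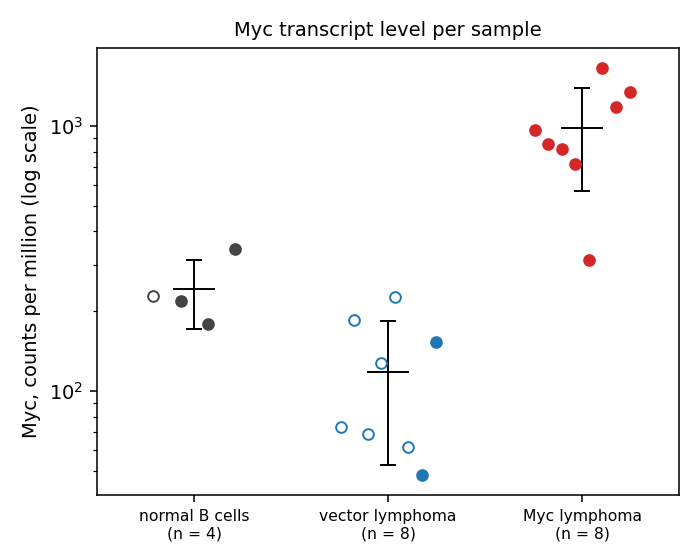
Myc CPM on a log axis for each sample of the 3 groups (n = 4, 8 and 8); open points are later runs, horizontal bars are group means and vertical bars 1 SD. The group means are 242, 118 and 979 CPM.

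The comparison of Myc with vector lymphomas asks what the addition of Myc changed within 1 lymphoma model. Genes for building ribosomes, making nucleotides and one-carbon units, and running mitochondria and mitosis were higher in Myc lymphomas, and genes that mark germinal centre B cells, mature B cells, NF-kB signalling and antigen presentation were lower. With an estimated correlation between the genes of a list 0 of the 25 list calls held, and within the earlier runs 0 of 36 oxidative phosphorylation genes and 0 of 13 mitochondrially encoded genes rose. Srm, which makes the polyamine spermidine, rose 5.13-fold (log2 fold change 2.36 ± 0.23 SE, adjusted p = 1.9e-07), and Shmt1, an enzyme of serine and one-carbon metabolism, rose 4.38-fold (2.13 ± 0.16, 7.4e-09). Neil1, a DNA repair enzyme of the germinal centre list, fell by 2.72 ± 0.23 on the log2 scale (adjusted p = 3.3e-08), and Cd22, an inhibitory receptor of B cells, fell by 2.29 ± 0.21 (7e-08). Of 17824 genes tested with edgeR's quasi-likelihood test, 4747 rose and 3907 fell at an adjusted p under 0.05 (n = 8 and 8), and 9832 had an unadjusted p under 0.05. Of these, 3169 rose and 1854 fell by at least 2-fold. The groups did not overlap in 11.5% of genes, while chance gives 0.016%. Within the earlier runs 549 genes rose and 814 fell (n = 8 and 2). Of the 8636 pooled calls that were tested there, 8450 kept their sign and 1279 were called with the same sign. These samples are part of the pooled ones. With the later runs as a term in the fit, 3382 genes were called.

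Ribosome-building genes were higher in Myc lymphomas. Of the 45 genes measured for ribosome biogenesis, 34 rose, 0 fell and 11 did not pass (34 rose adjusted over the list alone), with a median log2 fold change of 0.72 (camera adjusted p = 7.2e-11, adjusted p = 0.14 with an estimated correlation). Wdr12 rose 3.16-fold (1.66 ± 0.16, adjusted p = 1.4e-07) and Dkc1, which modifies ribosomal RNA, rose 2.82-fold (1.49 ± 0.17, 9.8e-07), while nucleolin (Ncl) had 0.33 ± 0.24 (0.25, or 0.86 and 0.22 within the earlier runs and 0.90 and 0.036 with the run term, a call). Within the earlier runs 17 of the 45 rose, with a median of 0.91. The cytosolic ribosomal proteins moved further: 46 of 51 rose and 0 fell (48 adjusted over the list alone, median 1.40, camera adjusted p = 2.7e-10, adjusted p = 0.36 with an estimated correlation). Rplp0 rose 3.78-fold (1.92 ± 0.30, 3.8e-05) and Rps28 8.88-fold (3.15 ± 0.53, 8.1e-05). Their median was 0.83 without Myc replicate 5, and within the earlier runs 0 of 51 rose (median 1.01). Many ribosomal protein genes have near-identical pseudogenes, so reads counted to them are uncertain.

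Metabolic genes rose as well. Nucleotide synthesis had 18 of 23 genes up and 1 down (the same counts adjusted over the list alone, median 0.87, camera adjusted p = 1.3e-07, adjusted p = 0.14 with an estimated correlation, 6 rose within the earlier runs, median 1.08). Uck2, which phosphorylates uridine and cytidine, rose 3.77-fold (1.91 ± 0.16, 2.9e-08), and Gart, of purine synthesis, rose 2.25-fold (1.17 ± 0.12, 2.5e-07). Serine and one-carbon metabolism had 9 of 14 up and 0 down (9 adjusted over the list alone, median 0.93, camera adjusted p = 5.1e-05, adjusted p = 0.14 with an estimated correlation, 4 rose within the earlier runs, median 0.88). Sfxn1, a serine carrier of mitochondria, was at 1.34 ± 0.12 (3.4e-08) and Shmt2 at 1.04 ± 0.13 (4e-06). Oxidative phosphorylation had 31 of 36 up and 0 down (32 adjusted over the list alone, median 0.97, camera adjusted p = 2.3e-08, adjusted p = 0.35 with an estimated correlation, 0 rose within the earlier runs, median 0.76). Mitochondrial translation and import had 24 of 31 up and 0 down (26 adjusted over the list alone, median 0.74, camera adjusted p = 1.3e-07, adjusted p = 0.30 with an estimated correlation, 3 rose within the earlier runs, median 0.80). Translation factors and tRNA synthetases had 17 of 29 up and 1 down (18 and 1 adjusted over the list alone, median 0.47, camera adjusted p = 2.7e-04, adjusted p = 0.32 with an estimated correlation, 1 rose within the earlier runs, median 0.61). Glycolysis had 11 of 20 up and 3 down (the same adjusted over the list alone, median 0.59, camera adjusted p = 0.044, adjusted p = 0.35 with an estimated correlation, 3 rose within the earlier runs), and Ldha, which makes lactate, rose 2.58-fold (1.37 ± 0.18, 5e-06). The glycolysis call ended without vector replicate 7 or Myc replicate 1, 4 or 7 (adjusted p = 0.052 to 0.074). Amino acid uptake and polyamine synthesis was not called (4 of 12 rose and 2 fell, adjusted p = 0.23), and Odc1 had 0.27 ± 0.23 (0.35).

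Cell-cycle genes were higher in Myc lymphomas. Of 34 mitosis genes 23 rose and 0 fell (24 adjusted over the list alone, median 0.68, camera adjusted p = 1.3e-07, adjusted p = 0.32 with an estimated correlation, 2 rose within the earlier runs, median 0.77). Cdc20 rose 2.39-fold (1.26 ± 0.19, 2.2e-05) and Cdk1, the kinase that drives entry into mitosis, 2.67-fold (1.42 ± 0.22, 3.9e-05). Of 35 DNA replication genes 23 rose and 2 fell (24 and 2 adjusted over the list alone, median 0.49, camera adjusted p = 2.2e-04, adjusted p = 0.37 with an estimated correlation, 3 rose within the earlier runs, median 0.77). G1 cyclins, kinases and inhibitors had 11 of 21 up and 2 down (the same adjusted over the list alone, median 0.65, camera adjusted p = 0.027, adjusted p = 0.32 with an estimated correlation, 1 rose within the earlier runs), a call that ended without vector replicate 7 (0.052). The members that rose include inhibitors of the cycle: Cdkn2a rose 3.09-fold (1.63 ± 0.29, 1.3e-04) and Cdkn1a 2.89-fold (1.53 ± 0.28, 1.7e-04). Trp53, which encodes p53, rose 1.88-fold (0.91 ± 0.17, 2.2e-04). These 3 genes were not called within the earlier runs (1.23, 1.09 and 0.67, adjusted p = 0.12 to 0.22).

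The germinal centre list fell as a whole. All 11 measured members fell (11 adjusted over the list alone), with a median of -3.25 (camera adjusted p = 6e-10, adjusted p = 0.14 with an estimated correlation), and 10 of the 11 fell within the earlier runs (median -3.55). Bcl6, the transcription factor that directs the germinal centre programme, fell from 212 ± 44.8 CPM to 44.1 ± 23.5 (-2.27 ± 0.26, 1.2e-06), Efnb1 fell by 2.87 ± 0.26 on the log2 scale (6.7e-08) and Rgs13 by 4.58 ± 0.52 (1e-06). Of 18 pan-B-cell genes 16 fell and 0 rose (16 fell and 1 rose adjusted over the list alone, median -1.49, camera adjusted p = 1.3e-08, adjusted p = 0.25 with an estimated correlation, 9 fell within the earlier runs, median -1.49). Bank1 fell by 2.03 ± 0.20 (1.5e-07). Ptprc, whose B220 form was used to collect the cells, fell by 0.79 ± 0.27 (0.02, -0.85 and 0.32 within the earlier runs). Cd79a, part of the B-cell receptor, fell by 1.00 ± 0.37 (0.031), a call that ended without vector replicate 7 or Myc replicate 1, 2 or 8 (0.057 to 0.07) and reached -1.56 without Myc replicate 5. Mature follicular B cell genes fell in 11 of 13 (11 adjusted over the list alone, median -1.27, camera adjusted p = 1.5e-06, adjusted p = 0.14 with an estimated correlation, 6 fell within the earlier runs, median -1.18). Cr2, a complement receptor, was down by 3.16 ± 0.30 (1.4e-07). Marginal zone and B-1 cell genes fell in 7 of 12 (8 adjusted over the list alone, median -0.81, camera adjusted p = 0.0011, adjusted p = 0.14 with an estimated correlation, 4 fell within the earlier runs, median -1.08). Genes of NK, neutrophil and plasmacytoid dendritic cells were higher in the same samples, as given below with their values.

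**Figure D3:**
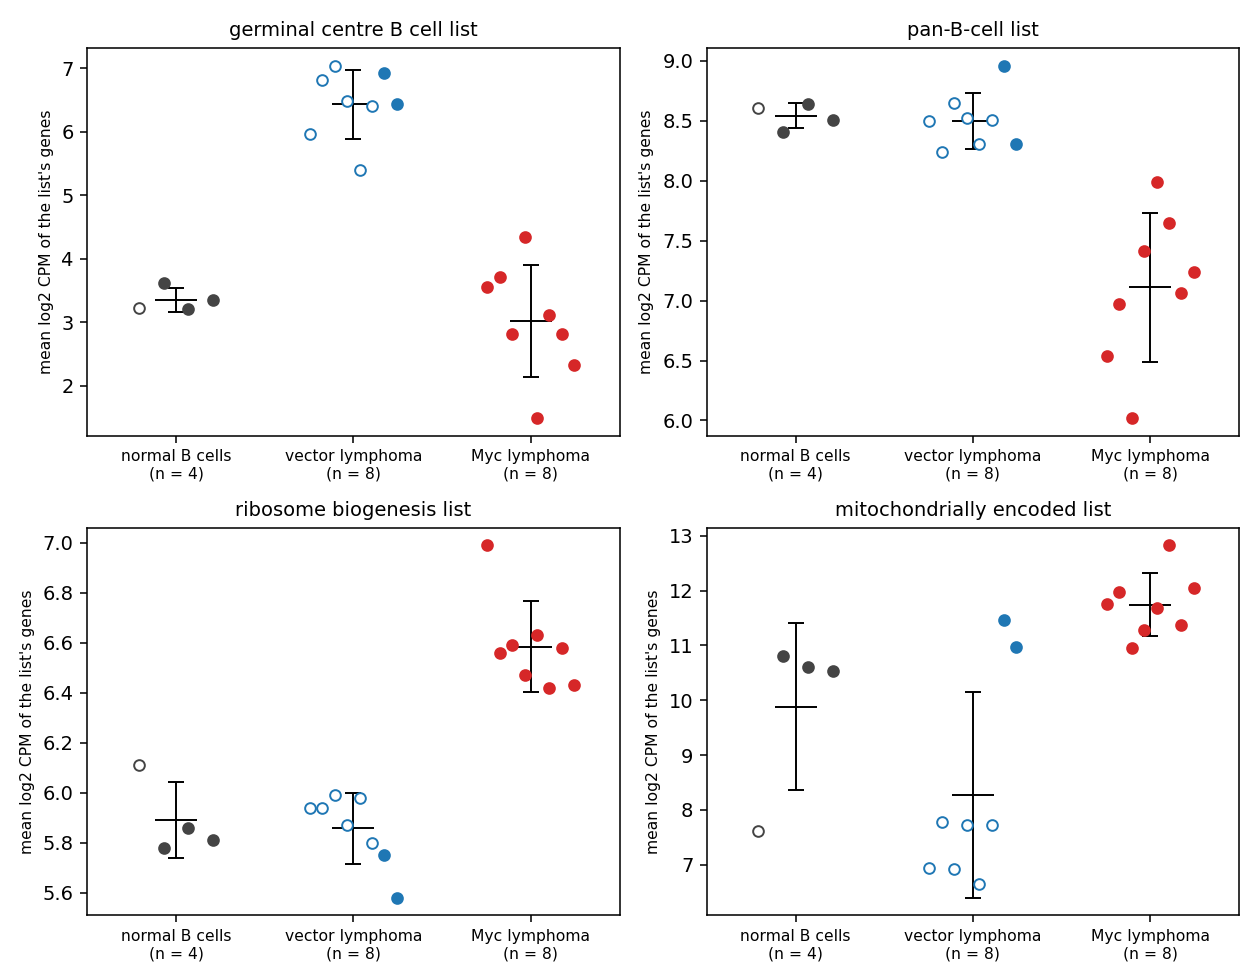
Mean log2 CPM of the genes of 4 lists (vertical axes) in each sample of the 3 groups (n = 4, 8 and 8); open points are later runs, horizontal bars are group means and vertical bars 1 SD. Germinal centre genes lie at 5.39 to 7.04 in vector lymphomas and at 1.49 to 4.34 in Myc lymphomas, and mitochondrially encoded genes lie at 7.78 or below in the 7 samples of the later runs and at 10.53 or above in the 13 of the earlier runs.

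Signalling, stress and antigen presentation genes were lower in Myc lymphomas. Of 15 NF-kB targets 13 fell and 1 rose (the same adjusted over the list alone, median -1.12, camera adjusted p = 3.4e-08, adjusted p = 0.14 with an estimated correlation, 7 fell within the earlier runs, median -0.93). Nfkb2 was down by 1.91 ± 0.16 (2.8e-08) and Cd40, a receptor for T-cell help, by 2.20 ± 0.23 (2.9e-07). MHC class II genes fell in 9 of 10 (9 adjusted over the list alone, median -1.40, camera adjusted p = 3.7e-06, adjusted p = 0.26 with an estimated correlation, 4 fell within the earlier runs, median -1.43), among them Ciita, their master regulator (-2.14 ± 0.24, 6.8e-07). MHC class I presentation genes fell in 6 of 11 (6 adjusted over the list alone, median -0.62, camera adjusted p = 0.0053, adjusted p = 0.24 with an estimated correlation, 0 fell within the earlier runs). All 14 genes of the immediate-early and dissociation response fell (14 adjusted over the list alone, median -2.50, camera adjusted p = 1.7e-07, adjusted p = 0.21 with an estimated correlation, 5 fell within the earlier runs, median -2.34). Members include Egr2 (-3.07 ± 0.39, 3.9e-06) and Hspa1a (-7.82 ± 0.77, 1.6e-07). This list also marks cells stressed during tissue handling. The unfolded protein and amino acid response had 9 of 19 down and 1 up (the same adjusted over the list alone, median -0.55, camera adjusted p = 0.016, adjusted p = 0.38 with an estimated correlation, 1 fell within the earlier runs). The member that rose was asparagine synthetase (Asns, 1.67 ± 0.25, 2e-05). Genes recurrently mutated in B cell lymphoma fell in 9 of 21 (9 adjusted over the list alone, median -0.58, camera adjusted p = 0.0016, adjusted p = 0.35 with an estimated correlation, 2 fell within the earlier runs). Its members Sesn1 (0.08 ± 0.24, 0.79) and Tnfrsf14 (-0.44 ± 0.29, 0.21) were not called.

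Markers of other cells differed between the groups, and RNA from mitochondria split by run. NK and cytotoxic cell genes rose in 9 of 10 (9 adjusted over the list alone, median 2.05, camera adjusted p = 4.8e-06, adjusted p = 0.14 with an estimated correlation, 4 rose within the earlier runs, median 1.57). Gzma was at 96.5 ± 83.2 against 5.02 ± 2.03 CPM (4.26 ± 0.42, 1.9e-07). Plasmacytoid dendritic cell genes, whose cells carry B220, rose in 7 of 8 and fell in 1 (the same adjusted over the list alone, median 2.63, camera adjusted p = 0.0028, adjusted p = 0.32 with an estimated correlation, 4 rose within the earlier runs, median 3.07). Ccr9 was at 67.4 ± 37.6 against 11.4 ± 5.68 CPM (2.57 ± 0.34, 5.2e-06). Neutrophil genes rose in 9 of 16 (10 adjusted over the list alone, median 2.38, camera adjusted p = 3.7e-05, adjusted p = 0.36 with an estimated correlation). Their median was 3.71 without vector replicate 8, and within the earlier runs 0 rose and 1 fell, with a median of 0.65 that was not called (0.56). All 13 mitochondrially encoded genes rose (13 adjusted over the list alone, median 2.40, camera adjusted p = 1.5e-06, adjusted p = 0.32 with an estimated correlation), and within the earlier runs 0 rose, with a median of 0.70. Their mean lay at 7.78 or below in all 7 later-run samples and at 10.53 or above in all 13 of the earlier runs, vector replicates 7 and 8 among them. Reads aligned to more than 1 place made up 22.2 to 40.3% in Myc lymphomas, 15.4 to 31.3% in vector lymphomas and 14.3 to 17.9% in normal samples.

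Of the 15 lists not called between Myc and vector lymphomas, 14 remain to be given. With members risen and fallen in that order, the pooled counts were 4 and 0 of 11 for erythroid genes (median 1.17, adjusted p = 0.07, called within the earlier runs at 2.23 and 1.5e-05), 7 and 1 of 13 for pro-B and pre-B cell genes (0.088) and 1 and 5 of 11 for plasma cell genes (0.052). Counts were 1 and 4 of 9 for activated and follicular helper T cells (0.053), 1 and 5 of 8 for conventional dendritic cells (0.075), 4 and 4 of 16 for T cells (0.64), 2 and 1 of 19 for macrophages and monocytes (0.77), 2 and 0 of 8 for megakaryocytes and platelets (0.59), and 3 and 1 of 13 for stromal and endothelial cells (0.71). For interferon response they were 8 and 4 of 23 (0.54), for p53 targets 8 and 4 of 20 (0.26), for cholesterol synthesis 5 and 2 of 19 (0.99), for the Bcl2 family 5 and 3 of 15 (0.76), and for Myc and its dimerisation network 3 and 2 of 10 (0.75). Adjusted over the list alone these counts were the same except for the Bcl2 family (5 and 4), p53 targets (8 and 5), cholesterol synthesis (1 and 2), interferon response (9 and 4), conventional dendritic cells (1 and 6) and stromal cells (2 and 1). In the earlier runs alone 7 lists not called in the pooled samples were called: amino acid uptake (median 0.37), plasma cell (-0.78), pro-B (1.57), interferon response (1.02), helper T (-0.87), conventional dendritic (-1.30) and erythroid. Among p53 targets Fas, a death receptor also in the germinal centre list, fell by 2.73 ± 0.29 (3.7e-07), and in the Bcl2 family Mcl1, which blocks apoptosis, fell by 0.98 ± 0.17 (1e-04).

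The genes with the largest changes and no overlap between groups were of mixed kinds. Those that rose furthest in Myc lymphomas included Esrp1, a splicing regulator of epithelial cells (5.06 ± 4.52 against 0.0262 ± 0.0622 CPM), Cd163l1 (131-fold, 7.04 ± 0.58, adjusted p = 2.2e-08), the receptor Epha3 (109-fold, 6.76 ± 0.81, 1.8e-06) and Stfa1 (95.6-fold, 6.58 ± 1.05, 4.6e-05), whose family of near-identical copies leaves its counts uncertain. Those that fell furthest included the heat-shock genes Hspa1a, Hspa1b and Hspa1l, of which the first pair are near-identical copies, and Emp2 (-6.81 ± 0.53, 1.1e-08), Cobl (-6.77 ± 0.70, 2.8e-07) and Slc4a3 (-5.65 ± 0.53, 1.1e-07). Of the 62 called genes that the text or its rule names for this comparison, 49 were called within the earlier runs. Besides Ptprc, Cd79a, Cdkn2a, Cdkn1a and Trp53, those not called there include Rplp0 (1.36, adjusted p = 0.15), Rps28 (2.11, 0.17), Ldha (1.19, 0.056), Cdk1 (1.29, 0.071), Asns (1.52, 0.065) and Mcl1 (-0.77, 0.13). Hspa1a kept its call there at -5.48. Of the 25 called lists 24 held within the earlier runs, all but neutrophil genes. As covariates, added after seeing the data, the immediate-early list left 1569 genes called and the neutrophil list 3376. The first ended 16 of 62 named calls, among them Ptprc, Cdkn1a, Cdkn2a, Trp53, Ldha, Stfa1, Rplp0, Rps28, Cdc20, Cdk1, Ciita, Egr2, Asns and Mcl1. That list, Egr2 included, fell in full, so the losses cannot tell it from group. With an estimated correlation camera called 0 of 40 lists, against 25 with the preset. By fry, which tests whether a list's genes move on balance 1 way and compares it with no other genes, all 25 calls held. Random splits of the 16 samples called a median of 15 lists, and 9 of 100 splits, the real one among them, called at least 25, so the number of lists called does not stand apart from other splits. No other split called more than 1 gene.

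The next comparison set vector lymphomas against normal B cells. Germinal centre, plasma cell, mitosis and stress response genes were higher in vector lymphomas, and NK cell genes were lower. With an estimated correlation 0 of the 24 list calls held (adjusted p = 0.072 or above), and erythroid genes rose in the same samples (11 of 11), a list whose covariate, added after seeing the data, left 143 genes called. Jchain, which joins antibody units, rose 13.7-fold (log2 fold change 3.77 ± 0.58 SE, adjusted p = 2.9e-04). Gzma, a protease of cytotoxic cells, fell by 2.93 ± 0.44 on the log2 scale (2.5e-04). By the edgeR test 1329 genes rose and 599 fell (n = 8 and 4), 4342 had an unadjusted p under 0.05, and 1093 rose and 449 fell by at least 2-fold. The groups did not overlap in 13.2% of genes, against 0.4% by chance. Within the earlier runs, with 2 vector and 3 normal samples, 115 genes rose and 8 fell. The count of 1928 was 1207, 1089 and 1118 without normal replicate 1, 3 or 4.

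Germinal centre and antibody-secretion genes rose. All 11 germinal centre genes rose (11 adjusted over the list alone, median 3.31, camera adjusted p = 4.8e-17, adjusted p = 0.072 with an estimated correlation), and 6 rose within the earlier runs (median 3.89). Efnb1 rose 9.9-fold (3.31 ± 0.35, 1.5e-05) and S1pr2, a receptor that holds cells in the germinal centre, 17.4-fold (4.12 ± 0.60, 2e-04). Bcl6 rose 2.02-fold (1.02 ± 0.32, 0.045), a call that ended without any 1 of normal replicates 1 to 4 or vector replicates 2, 3, 4, 6 or 7 (0.054 to 0.11). Plasma cell genes rose in 7 of 11 (10 adjusted over the list alone, median 1.70, camera adjusted p = 7.5e-09, adjusted p = 0.10 with an estimated correlation, 0 rose within the earlier runs, median 1.84), and Sdc1, a plasma cell surface protein, rose 6.81-fold (2.77 ± 0.39, 1.2e-04). Pan-B-cell genes were not called (0 of 18 by edgeR, median -0.04, adjusted p = 0.97). Nor were mature follicular genes called (2 of 13 fell, 0.08), although Cr2 fell by 1.72 ± 0.33 (0.002), and the list was called downward within the earlier runs (median -0.43, adjusted p = 0.0036). Marginal zone and B-1 cell genes fell in 3 of 12 (5 fell and 2 rose adjusted over the list alone, median -0.43, camera adjusted p = 0.027, adjusted p = 0.32 with an estimated correlation). Cd1d1 was down by 1.44 ± 0.20 (1.1e-04). The list was not called within the earlier runs (median -0.34, 0.18).

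Proliferation and stress genes rose too. Mitosis genes rose in 30 of 34 (33 adjusted over the list alone, median 1.18, camera adjusted p = 1.6e-22, adjusted p = 0.10 with an estimated correlation, 0 rose within the earlier runs, median 1.04). Plk1 was up 2.93-fold (1.55 ± 0.23, 2.4e-04). DNA replication genes rose in 16 of 35 (26 adjusted over the list alone, median 0.70, camera adjusted p = 6e-14, adjusted p = 0.13 with an estimated correlation, 0 within the earlier runs, median 0.54). The unfolded protein and amino acid response rose in 12 of 19 (15 adjusted over the list alone, median 1.08, camera adjusted p = 6.1e-12, adjusted p = 0.072 with an estimated correlation, 2 within the earlier runs, median 0.94). Asns was up 11.5-fold (3.53 ± 0.36, 1.2e-05) and Atf4, its transcription factor, 2.6-fold (1.38 ± 0.22, 4.7e-04). Translation factors and tRNA synthetases rose in 7 of 29 (8 adjusted over the list alone, median 0.35, camera adjusted p = 3.4e-05, adjusted p = 0.25 with an estimated correlation). Of 45 ribosome biogenesis genes 0 changed by edgeR (median 0.01, mean -0.03, camera adjusted p = 0.77). Cdkn2a rose 5.08-fold (2.34 ± 0.40, 6.9e-04) and Odc1 3.69-fold (1.88 ± 0.31, 5.8e-04). Cdkn1a rose 2.5-fold (1.32 ± 0.35, 0.018), a call that ended without normal replicate 1 (0.06), and Ccnd2, a G1 cyclin, fell by 1.33 ± 0.27 (0.0035). Shmt2 rose by 0.66 ± 0.17 on the log2 scale (0.013). Ldha (0.01 ± 0.22, 0.98), Ncl (0.40 ± 0.30, 0.43), Trp53 (-0.40 ± 0.20, 0.24), Cd79a (0.18 ± 0.45, 0.85), Ptprc (-0.33 ± 0.32, 0.57), Sesn1 (-0.65 ± 0.29, 0.16) and Tnfrsf14 (0.49 ± 0.36, 0.43) were not called.

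Smaller called lists were cholesterol synthesis (5 of 19 rose, 7 adjusted over the list alone, median 0.49, adjusted p = 0.25 with an estimated correlation) and, with values in the same order, glycolysis (4 of 20 rose and 1 fell, 5 and 1 adjusted over the list alone, 0.52, 0.25), nucleotide synthesis (5 of 23, 6 adjusted over the list alone, 0.17, or 0.29 without normal replicate 1, 0.37) and p53 targets (5 of 20, 5 adjusted over the list alone, 0.49, 0.25). Amino acid uptake and polyamine synthesis rose in 3 of 12 (4 rose and 1 fell adjusted over the list alone, median 0.11, 0.17 and 0.21 without normal replicates 3 and 4, adjusted p = 0.37 with an estimated correlation), and Slc3a2, part of an amino acid carrier, rose 2.95-fold (1.56 ± 0.19, 4.3e-05). Serine and one-carbon metabolism rose in 3 of 14 (4 adjusted over the list alone, median 0.47, camera adjusted p = 0.043, adjusted p = 0.38 with an estimated correlation), a call that ended without normal replicate 2 or vector replicate 2, 3 or 7 (0.051 to 0.057). MHC class II was called with 0 of 10 members passing edgeR (median 0.58, adjusted p = 0.46 with an estimated correlation). Of the 24 called lists 15 held within the earlier runs, 8 were lost (nucleotide synthesis, serine and one-carbon metabolism, amino acid uptake, p53 targets, marginal zone, MHC class II, conventional dendritic and macrophage) and 1 reversed. Called only there were neutrophil genes (upward) and, downward, mature follicular, ribosome biogenesis (median -0.12, adjusted p = 0.028), pro-B (-0.54, 0.01) and interferon response genes (-0.59, 0.0011). Random splits of these 12 samples called a median of 16 lists, and 3 of 100 called at least 24. By fry 20 held, and MHC class II, T cell, macrophage and mitochondrially encoded genes did not (0.059 to 0.21). Not called were ribosomal proteins (median -0.13, adjusted p = 0.23), mitochondrial translation and import (0.01, 0.96), oxidative phosphorylation (0.08, 0.55), G1 genes (4 of 21 rose and 2 fell, 0.19), Myc network (0.79), Bcl2 family (0.22), pro-B (2 of 13 fell, 0.058), MHC class I (0.14), interferon response (0.063) and megakaryocyte genes (0.79). For NF-kB targets (median -0.07, mean 0.02, 0.96) and recurrently mutated genes (-0.04 and 0.33, 0.64) the median and the upward test differ in sign.

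Markers of other cells also differed. Erythroid genes rose in 11 of 11 (11 adjusted over the list alone, median 3.15, and 5.36 without normal replicate 2, camera adjusted p = 6e-14, adjusted p = 0.10 with an estimated correlation, 0 rose within the earlier runs, median 1.55). Alas2, of haem synthesis, was at 639 ± 333 against 33.3 ± 49.6 CPM (4.26 ± 0.93, 0.0051), and lost its call within the earlier runs (1.89, 0.7). NK and cytotoxic genes fell in 7 of 10 (9 adjusted over the list alone, median -1.40, camera adjusted p = 2.2e-08, adjusted p = 0.072 with an estimated correlation, 0 within the earlier runs, median -1.19). Ncr1 was down by 2.57 ± 0.34 (7.2e-05). T cell genes fell in 3 of 16 (3 adjusted over the list alone, median -0.60, camera adjusted p = 0.0027, adjusted p = 0.39 with an estimated correlation). Cd8a was down by 1.49 ± 0.28 (0.0017). Activated and follicular helper T cell genes rose in 3 of 9 (3 adjusted over the list alone, median 0.78, camera adjusted p = 0.0079, adjusted p = 0.34 with an estimated correlation). Pdcd1 was up 4.97-fold (2.31 ± 0.45, 0.0023). Conventional dendritic cell genes fell in 2 of 8 (2 adjusted over the list alone, median -0.61, adjusted p = 0.13 with an estimated correlation). With values in the same order, plasmacytoid dendritic cell genes fell in 2 of 8 (3, -1.0, 0.37) and stromal and endothelial genes in 2 of 13 (4 fell and 1 rose, -0.76, 0.34). Macrophage and monocyte genes fell in 1 of 19 (1 adjusted over the list alone, median -0.30, camera adjusted p = 0.044, adjusted p = 0.57 with an estimated correlation), a call that ended without normal replicate 2 or 4 or vector replicate 4, 5, 6 or 7 (0.051 to 0.33). The macrophage median was -0.11 without normal replicate 2 and -0.53 without vector replicate 8. Neutrophil genes had a median of 1.42 and 0 calls in edgeR (camera adjusted p = 0.81), and 2.84 within the earlier runs (7.3e-10). The immediate-early and dissociation list rose in 7 of 14 (7 adjusted over the list alone, median 1.61, and 2.57 without normal replicate 4, camera adjusted p = 1.2e-06, adjusted p = 0.25 with an estimated correlation, 0 within the earlier runs, median 1.01). Mitochondrially encoded genes had 0 of 13 members called by edgeR, with a camera call downward (median -0.79, and -1.55 and -1.26 without vector replicates 7 and 8, camera adjusted p = 0.0025, adjusted p = 0.46 with an estimated correlation), and the list was called upward within the earlier runs (0.63, 0.022).

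Among the genes with the largest changes, Thsd7a (5.33 ± 2.29 against 0.019 ± 0.026 CPM), Tgfa, a growth factor (156-fold, 7.29 ± 0.84, 2.4e-05), Cobl (115-fold, 6.84 ± 0.95, 1.1e-04) and Arhgap8 (89.2-fold, 6.48 ± 0.78, 3.5e-05) rose. Those that fell were mostly pancreatic digestive enzymes, such as Try4 (-4.88 ± 1.27, 0.015), together with the NK receptor gene Klra4 (-3.90 ± 0.68, 9.6e-04). The trypsin and Klra genes belong to families of near-identical copies, so their counts are uncertain. The calls for Pnlip, Cpb1, Rnase1, Prss2 and Try5, also enzymes of the pancreas, each ended without normal replicate 1 (0.055 to 0.093), and some ended without normal replicates 2, 3 or 4 or vector replicates 2, 3, 4, 6 or 8 (0.051 to 0.067). Of the 53 called genes named for this comparison, 16 were called within the earlier runs. In the text those are Cdkn2a, Thsd7a, Tgfa, Cobl, Arhgap8, Efnb1, S1pr2, Asns, Slc3a2 and Cd8a. The other genes called in the text lost their call there, among them Jchain (3.55, adjusted p = 0.075), Sdc1 (2.04, 0.12), Odc1 (1.47, 0.17), Plk1 (1.41, 0.087), Ccnd2 (-1.47, 0.29), Cr2 (-1.36, 0.42) and Gzma (-3.67, 0.074). The erythroid covariate ended 34 of the 53 calls, but it nearly parts the groups, so losses cannot tell it from group. Kept in the text were Jchain, Gzma, Efnb1, S1pr2, Asns, Slc3a2, Ncr1, Pdcd1, Thsd7a, Tgfa, Cobl, Arhgap8 and Klra4.

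The last comparison set Myc lymphomas against normal B cells. Proliferation, nucleotide, translation and mitochondrial genes were higher in Myc lymphomas, and B-cell identity and NF-kB genes were lower, while the germinal centre list was not called. With an estimated correlation 0 of the 28 list calls held, and all 28 held within the earlier runs. Asns rose 36.7-fold (105 ± 38.8 against 2.86 ± 1.35 CPM, log2 fold change 5.20 ± 0.39, adjusted p = 4.8e-08), Cdkn2a 15.7-fold (3.97 ± 0.43, 1.7e-06) and Slc7a5, an amino acid carrier, 5.8-fold (2.54 ± 0.29, 2.7e-06). Ms4a1, which encodes CD20, fell by 2.54 ± 0.29 (3.6e-06) and Cr2 by 4.88 ± 0.35 (2.6e-08). By the edgeR test 3831 genes rose and 3194 fell (n = 8 and 4), 8741 had an unadjusted p under 0.05, and 2898 rose and 1684 fell by at least 2-fold. The groups did not overlap in 27.4% of genes, against 0.4% by chance. In the earlier runs alone (8 and 3 samples) 2345 rose and 1475 fell, and 3724 of the pooled calls were called there with the same sign. With the erythroid list as a covariate, added after seeing the data, 140 genes were called and the Myc gene was not (1.89, adjusted p = 0.32); all lymphomas but vector replicate 7 lay above every normal sample for that list.

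Growth and cell-cycle lists rose together. Mitosis genes rose in 33 of 34 (34 adjusted over the list alone, median 1.87, camera adjusted p = 3.3e-22, adjusted p = 0.087 with an estimated correlation, 32 within the earlier runs). Ccnb1 was up 6.82-fold (2.77 ± 0.29, 1.2e-06). DNA replication genes rose in 30 of 35 (30 adjusted over the list alone, median 1.27, camera adjusted p = 8.5e-14, adjusted p = 0.099 with an estimated correlation, 28 within the earlier runs). Orc1 was up 7.88-fold (2.98 ± 0.36, 5.2e-06). Nucleotide synthesis rose in 19 of 23 (20 adjusted over the list alone, median 1.22, camera adjusted p = 5.6e-11, adjusted p = 0.087 with an estimated correlation, 19 within the earlier runs). Serine and one-carbon metabolism rose in 11 of 14 (12 adjusted over the list alone, median 1.57, camera adjusted p = 7.7e-07, adjusted p = 0.087 with an estimated correlation, 11 within the earlier runs). Shmt2 was at 1.69 ± 0.17 (1e-06). Ribosome biogenesis rose in 29 of 45 (35 adjusted over the list alone, median 0.69, camera adjusted p = 3.5e-10, adjusted p = 0.11 with an estimated correlation, 25 within the earlier runs). Nhp2 was up 5.17-fold (2.37 ± 0.37, 6.6e-05). Translation factors and tRNA synthetases rose in 25 of 29 (26 adjusted over the list alone, median 0.79, camera adjusted p = 3.5e-10, adjusted p = 0.087 with an estimated correlation, 23 within the earlier runs). Gars was up 2.52-fold (1.33 ± 0.16, 6.3e-06). Oxidative phosphorylation rose in 27 of 36 (29 adjusted over the list alone, median 1.10, adjusted p = 0.39 with an estimated correlation, 15 within the earlier runs) and, with values in the same order, mitochondrial translation and import in 25 of 31 with 1 down (27 and 1, 0.92, 0.26, 13), and ribosomal proteins in 32 of 51 (41, 1.22, and 0.72 without Myc replicate 5, 0.43, 2). In that order, leaving off the count of the earlier runs, glycolysis rose in 11 of 20 with 2 down (13 and 2, 0.86, 0.099), amino acid uptake in 8 of 12 with 1 down (8 and 2, 0.74, 0.26), and G1 genes in 11 of 21 with 3 down (11 and 4, 0.75, 0.22). Cholesterol synthesis rose in 7 of 19 (7, 0.45, 0.39), p53 targets in 9 of 20 with 1 down (10 and 3, 0.43, 0.28) and the unfolded protein and amino acid response in 9 of 19 with 2 down (9 and 2, 0.53, 0.43). Ldha (1.38 ± 0.23, 1.3e-04), Odc1 (2.15 ± 0.32, 4.2e-05) and Cdkn1a (2.85 ± 0.39, 1.7e-05) rose. Trp53 (0.51 ± 0.21, 0.057), Ncl (0.74 ± 0.30, 0.056, but called within the earlier runs at 1.05 and 0.042), Cd79a (-0.82 ± 0.44, 0.14), Sesn1 (-0.57 ± 0.29, 0.12) and Tnfrsf14 (0.05 ± 0.35, 0.92) did not pass.

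B-cell lists fell. Pan-B-cell genes fell in 13 of 18 (13 adjusted over the list alone, median -1.34, camera adjusted p = 3.5e-08, adjusted p = 0.24 with an estimated correlation, 11 within the earlier runs). Mature follicular genes fell in 11 of 13 (11 adjusted over the list alone, median -1.70, camera adjusted p = 7.3e-08, adjusted p = 0.09 with an estimated correlation, 11 within the earlier runs) and NF-kB targets in 13 of 15 (13 adjusted over the list alone, median -0.98, camera adjusted p = 4.6e-08, adjusted p = 0.087 with an estimated correlation, 11 within the earlier runs). Examples were Ptprc (-1.12 ± 0.32, 0.0088), Bank1 (-2.25 ± 0.22, 7.1e-07), Btg1 (-1.93 ± 0.24, 9.1e-06) and Nfkb2 (-1.98 ± 0.18, 3.7e-07). Marginal zone and B-1 genes fell in 7 of 12 and rose in 1 (8 and 1 adjusted over the list alone, median -1.20, adjusted p = 0.087 with an estimated correlation). Dtx1, a regulator of Notch signalling, was at -2.42 ± 0.20 (1.1e-07). With values in the same order MHC class II fell in 4 of 10 (4, -0.72, 0.39) and recurrently mutated genes in 9 of 21 with 2 up (11 and 2, -0.72, 0.43). Germinal centre genes had 0 up and 1 of 11 down (median 0.16, mean -0.01 and a downward test, which differ in sign, camera adjusted p = 0.58): Bcl6 fell by 1.25 ± 0.30 (0.0027). Plasma cell genes rose in 8 of 11 (9 rose and 1 fell adjusted over the list alone, median 1.33, camera adjusted p = 0.0081, adjusted p = 0.39 with an estimated correlation). Jchain was up 4.5-fold (2.17 ± 0.52, 0.003). Among Bcl2 family genes, where 6 of 15 rose and 2 fell without a call for the list (0.24), Bcl2l11, which promotes apoptosis, rose 4.15-fold (2.05 ± 0.45, 0.0014), Bcl2l1, which blocks it, rose 4.64-fold (2.22 ± 0.47, 0.0011) and Mcl1 fell by 1.39 ± 0.20 (2.7e-05). With the erythroid covariate Bcl2l1 had -0.94 (0.53).

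Markers of other cells changed as well. Erythroid genes rose in 11 of 11 (11 adjusted over the list alone, median 3.87, and 6.41 without normal replicate 2, camera adjusted p = 1.7e-09, adjusted p = 0.13 with an estimated correlation, 10 within the earlier runs). Gata1 was up 14.6-fold (3.87 ± 0.64, 1.3e-04). Neutrophil genes rose in 13 of 16 (13 adjusted over the list alone, median 3.68, camera adjusted p = 9.2e-05, adjusted p = 0.39 with an estimated correlation, 12 within the earlier runs). Camp was up 25.9-fold (4.70 ± 1.29, 0.0074). Conventional dendritic cell genes fell in 6 of 8 and rose in 1 (7 and 1 adjusted over the list alone, median -1.70, camera adjusted p = 3.4e-04, adjusted p = 0.099 with an estimated correlation). Cd209a was at -2.95 ± 0.37 (8.8e-06). T cell genes fell in 6 of 16 (6 fell and 1 rose adjusted over the list alone, median -0.56, camera adjusted p = 0.0084, adjusted p = 0.43 with an estimated correlation). The immediate-early list fell in 4 of 14 (4 adjusted over the list alone, median -1.13, camera adjusted p = 0.017, adjusted p = 0.47 with an estimated correlation), a call that ended without normal replicate 4 (-0.38, 0.076) or Myc replicate 5 (0.053). Mitochondrially encoded genes rose in 1 of 13 (1 adjusted over the list alone, median 1.58, camera adjusted p = 0.0081, adjusted p = 0.51 with an estimated correlation), a call that ended without normal replicate 1 (1.27, 0.067). It held within the earlier runs (4 of 13 rose, median 1.27, 6.9e-05). Not called were NK and cytotoxic (5 of 10 rose and 1 fell, 0.24), plasmacytoid dendritic (4 of 8 rose and 1 fell, 0.13), interferon response (4 of 23 rose and 6 fell, median 0.11 and mean 0.28 against a downward test, 0.55), macrophage, megakaryocyte, stromal, helper T, pro-B, MHC class I and Myc network genes (adjusted p = 0.071 to 0.95). By fry 27 of the 28 called lists held, the exception being the mitochondrially encoded genes (0.072). Random splits of these 12 samples called a median of 17 lists and at most 27.

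The largest rises against normal B cells included Kcnc4, a potassium channel (5.51 ± 2.59 CPM, with no counts in any normal sample), Stfa2 (16.1 ± 10.1 against 0.00438 ± 0.00876 CPM), Ankrd36 (387-fold, 8.60 ± 1.11, adjusted p = 1.2e-05) and the eosinophil peroxidase Epx (192-fold, 7.59 ± 1.13, 4.7e-05). The largest falls included the peptidase Ace (-4.67 ± 0.36, 4.8e-08), S1pr3 (-4.16 ± 0.40, 4.7e-07) and Klra4 (-6.28 ± 0.77, 6.4e-06). The pancreatic enzymes Cel, Cela2a, Cela3b and Pnlip also fell (-4.54 to -4.31, adjusted p = 0.031 to 0.035), calls that ended without normal replicate 1 (0.074 to 0.1) and for some without normal replicate 2 or 4 or Myc replicate 4 (0.05 to 0.056). Without Myc replicate 6 the values were -9.53 for Cela2a and -9.46 for Pnlip, while Cel and Cela3b had 0 and 2 counts left in that group, so no fold change is given. Of the 60 called genes named here, 55 were called within the earlier runs, the others being the 4 pancreatic enzymes and Ptprc (-1.02, adjusted p = 0.091). The erythroid covariate ended 42 of the 60 calls, with the same limit. Kept in the text were Cdkn2a, Asns, Cr2, Kcnc4, Klra4, Ace, S1pr3, Shmt2, Ccnb1, Bank1, Nfkb2, Dtx1 and Cd209a.

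Changes against normal B cells shared by both lymphoma groups were counted. Both comparisons called 787 genes as risen and 277 as fallen, 1064 in all, among them Asns, Cdkn2a and Jchain (risen) and Cr2 and Klra4 (fallen). Independent lists of the same sizes would share 285.6 and 107.3. In 20 simulations with no gene changed the means were 0.05 and 0 (at most 1), which cannot show what shared normal samples add. With the normal samples split 2 and 2 between the comparisons, the means over 6 splits were 167.5 risen (79 to 268) and 57.5 fallen (46 to 70), against 36.3 and 13.1 for independent lists. The earlier runs alone shared 50 risen and 2 fallen. In opposite directions, 74 genes rose in vector and fell in Myc lymphomas and 37 did the reverse, and all 111 were also called between the lymphoma groups.

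Immunoglobulin counts were used to ask whether the lymphomas had switched antibody class or favoured single V genes. Switched isotypes made up 61.7 ± 12.8% of heavy chain constant gene counts in vector lymphomas (SD, n = 8) and 5.78 ± 4.15% in normal B cells (SD, n = 4). All 8 vector lymphomas lay above all 4 normal samples (exact two-sided permutation p = 0.002, the smallest possible, adjusted p = 0.012 over 12 tests). In Myc lymphomas the share was 44.3 ± 21.0% (exact permutation p = 0.01, adjusted p = 0.03 against normal), higher than in every normal sample in 7 of 8. The Myc against normal call ended without normal replicate 1, 3 or 4 or Myc replicate 2 or 4 (adjusted p = 0.055 each). Lambda light chain counts were 3.3 ± 2.14% of light chain counts in vector lymphomas and 10.7 ± 1.49% in normal B cells (exact permutation p = 0.002, adjusted p = 0.012), with all 8 below all 4. They were 6.26 ± 5.16% in Myc lymphomas (adjusted p = 0.18 against normal, exact permutation, 0.0091 without Myc replicate 5, which held 18.0%). The largest kappa V gene held 32.8 ± 20.4% of kappa V counts in vector lymphomas, 14.2 ± 5.42% in Myc lymphomas and 8.56 ± 2.61% in normal B cells. The lymphoma groups differed (exact permutation p = 0.0033, adjusted p = 0.013, 0.052 without Myc replicate 2), and vector lymphomas against normal had an adjusted p of 0.10 (exact permutation, 0.036 without vector replicate 4). The largest heavy chain V gene held 18.3 ± 1.2%, 31.9 ± 21.1% and 24.1 ± 8.64% in normal, vector and Myc samples (adjusted p = 0.26 to 0.44, exact permutation), and without vector replicate 4 the differences went from -7.77 to -0.63 for Myc against vector and from 13.55 to 6.4 for vector against normal. In vector replicate 4 it was Ighv7-1 with 81.9% of counts (95% exact Clopper-Pearson interval 81.7 to 82.1%), and Igkv5-39 held 72.5% of kappa counts (72.3 to 72.6%). These intervals cover counting error only. Switched shares of Myc and vector lymphomas did not differ at the threshold (exact permutation adjusted p = 0.13, 0.026 without Myc replicate 1). In the earlier runs alone the differences were 54.1 percentage points in switched share for vector against normal and 37.7 for Myc against normal, -8.43 in lambda share for vector against normal and -10.45 in kappa share for Myc against vector, each with an adjusted p of 0.2 by exact permutation. With 2 vector and 3 normal samples the smallest possible p is 0.1, so those 2 tests could not pass. Only 27 heavy V, 59 kappa V, 6 heavy constant and 1 lambda constant genes of the table could be used, so V gene shares are shares of those genes.

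**Figure D4:**
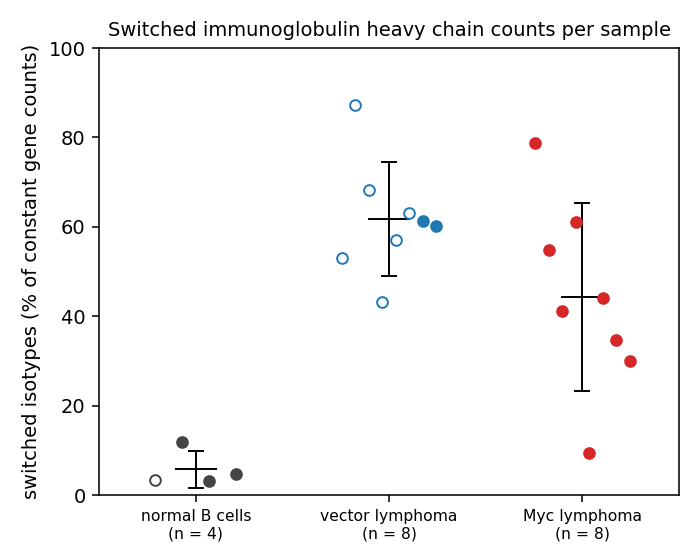
Share of heavy chain constant gene counts from switched isotypes (vertical axis, percent) in each sample of the 3 groups (n = 4, 8 and 8); open points are later runs, horizontal bars are group means and vertical bars 1 SD. The means are 5.78% in normal B cells, 61.7% in vector lymphomas and 44.3% in Myc lymphomas.

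Within a lymphoma group the Myc level was set against the mean log2 CPM of ribosome biogenesis genes, to ask whether lymphomas with more Myc transcript held more of them. In the 8 vector lymphomas Pearson's r was 0.12 (two-sided exact permutation p = 0.79, adjusted 0.79) and Spearman's rho 0.33 (p = 0.43, adjusted 0.43). Without the 2 samples farthest from the median Myc level, replicates 5 and 7, r was -0.32 (exact permutation p = 0.61). It was -0.10 without replicate 5, -0.06 without replicate 7 and 0.58 without replicate 8. In the 8 Myc lymphomas r was -0.23 (exact permutation p = 0.50, adjusted 0.79) and rho -0.55 (p = 0.17, adjusted 0.34), and r was -0.07 without replicates 5 and 6 (p = 0.89) and -0.69 without replicate 1 (exact permutation p = 0.072). No relation was detectable in either group of 8. The earlier runs held 2 vector lymphomas, too few for a correlation, and all 8 Myc lymphomas.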

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

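Values far from the rest of their group were sought by Dixon's test at the 95% level on log2 CPM, in groups of 4 and 8. Chance flags about 1 in 20 groups; here 41 of 398 group tests of named genes and 55 of 530 in all were flagged, about 1 in 10. The log2 scale was chosen after the CPM scale had given more flags. The tests of all 3 patterns weighed below were chosen only after the results were seen, and 2 of their predictions were reworded and then set back.

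Myc replicate 5 lay far from the other Myc lymphomas in log2 CPM of Ptprc (6.82), Kcnc4 (-0.532) and Nuggc (-4.43), which were lowest there, and of Rplp0 (13.8), Nhp2 (8.69) and Ncr1 (4.43), which were highest. It held the highest mean of ribosomal proteins (12) and oxidative phosphorylation (8.0), the lowest of amino acid uptake (6.27), p53 targets (4.03) and recurrently mutated genes (4.54), and the highest lambda share (18.0%). Myc replicate 1 held the highest Dkc1 (8.25) and ribosome biogenesis mean (6.99) and the lowest Cr2 (2.0) and MHC class I mean (7.83).

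Vector replicate 8 held the lowest Hspa1a (4.27), Hspa1b (2.93) and Hspa1l (1.29) of its group. Vector replicate 2 held the highest Esrp1 (-2.16), Lingo3 (-0.88), BC100530 (2.29) and Stfa2 (0.406) and the lowest Cd1d1 (3.04). Vector replicate 7 was lowest in Slc7a5 (5.85) and in the Myc network (5.27) and plasmacytoid dendritic (1.98) means, vector replicate 5 highest in Sesn1 (6.89), and vector replicate 4 highest in its largest heavy chain V gene (81.9%).

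Normal replicate 2 was highest in Lingo3 (-3.97), Plk1 (3.81), Hba-a2 (6.77), Mcm10 (3.94) and Gata1 (3.73) and in the mitosis (4.62) and erythroid (6.17) means. Normal replicate 1 was lowest in Klk1b27 (0.0882), Sostdc1 (-1.87) and Phlda3 (-0.144) and highest in Gart (6.6), BC100530 (-3.34) and Stfa2 (-3.97). Normal replicate 4 was lowest in Ldha (7.83) and Epha3 (-3.89), and normal replicate 3 in Emp2 (-2.37) and Trpm5 (0.765).

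Some results called between the lymphoma groups went opposite ways against normal B cells. Their median log2 fold changes, Myc against vector, were -1.40 for MHC class II, -2.50 for immediate-early genes and 2.40 for mitochondrially encoded genes. Gene values were -2.27 for Bcl6, 7.04 for Cd163l1, -7.82 for Hspa1a, -7.61 for Hspa1b and -7.43 for Hspa1l. Others were -6.81 for Emp2, -2.21 for Dnajb9, 4.26 for Gzma and 3.54 for Klrb1c. In the earlier runs the mitochondrially encoded list was called upward in both lymphoma groups against normal (0.63 and 1.27), and MHC class II lost its call for vector against normal (0.063). Outside the gene counts, reads aligned to more than 1 place reached 40.3% and lay above every normal sample in 15 of the 16 lymphomas.

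Mitochondrially encoded genes were higher in Myc than in vector lymphomas, and normal replicate 1 was lowest in mt-Co1 (11.5) and in the list mean (7.61). Within vector lymphomas the later runs lay below the earlier on the log2 scale (-3.92, exact two-sided permutation p = 0.036, the smallest possible). Normal replicate 1, the later-run normal sample, lay 3.04 below the mean of the other 3. The pooled Myc minus vector difference was 3.47, with 6 of 8 vector lymphomas later-run. Within the earlier runs the median log2 fold change was 0.70 and the difference in means 0.53 (95% interval of a t test with equal variances -0.47 to 1.53, n = 8 and 2). The Myc group as the whole cause is set aside, since this interval lies below the pooled 3.47. The levels parted by run, as a run batch would give. It stays open, since earlier-run vector lymphomas share a prefix of their own and only 1 normal library differs in run within 1 prefix. Whether the Myc group adds a smaller part also stays open, with only 2 such vector lymphomas.

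Pan-B-cell genes were lower in Myc than in vector lymphomas, which a lower share of B cells could produce. An even dilution would raise the markers of all other cell types alike. Instead their 10 lists moved apart, with an SD over the lists of 1.27 (exact permutation p = 1.6e-04, the smallest possible). In the earlier runs alone they ran from -1.40 (helper T cells) to 2.57 (plasmacytoid dendritic cells), with an SD of 1.35 (exact permutation p = 0.022, the smallest possible with 2 vector samples). A dilution raising all other types alike is set aside. An uneven one, which can give this spread, stays open, such as more NK or B220-carrying plasmacytoid dendritic cells. A run batch is also set aside, since the median was -1.49 within the earlier runs.

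Pancreatic enzyme genes were higher in normal samples, and Myc replicate 6 was highest of its group in Pnlip (4.51), Cpb1 (3.66), Rnase1 (2.15), Cel (3.57), Cela2a (3.59) and Cela3b (2.53). Pancreatic tissue carried along with the spleen might explain this: of 13 measured genes of a separate list of 17 acinar genes, 8 fell and 0 rose in vector lymphomas against normal (median -4.44), and 6 fell in Myc lymphomas. Profiles over these genes correlated at 0.94 to 0.99 between normal samples and at 0.93 with the normal mean for Myc replicate 6. Myc replicate 5, the next lymphoma by sum (57.5 after 104 CPM), correlated at 0.46 and held 0.602 CPM of Pnlip and 0 of Cpb1. A run batch is set aside, since normal replicate 1 of the later runs held the highest sum (213 CPM, against 173, 76.6 and 114 in the others). Pancreatic tissue and expression in the spleen cannot be told apart without samples of pancreas or whole spleen.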

How the results depend on the processing

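Alternatives were fixed before the data were examined, except covariates for the erythroid, neutrophil and immediate-early lists and for reads aligned to more than 1 place, autosomal genes and fry, which were chosen after seeing the data. Where a result moved, the cause was not tested unless fewer samples or a stricter threshold made it. For Myc against vector lymphomas 8654 genes became 3382 with the later-run covariate, 1363 in the earlier runs only, 5638 without prefix AO56 (vector 4 to 6), 3376 with the neutrophil and 1569 with the immediate-early covariate, and 5023 with an absolute log2 fold change of at least 1. For vector against normal 1928 became 8372 by limma-voom with weights, 3503 with only 2 groups in the fit, 1225 with the later-run covariate, 123 in the earlier runs, 981 with correlation within prefix, 821 without prefix AO55, 2912 without E205, 143 with the erythroid covariate and 779 at adjusted p under 0.01; without single replicates it was 1089 to 2139. For Myc against normal 7025 became 3820 in the earlier runs, 4372 with correlation within prefix, 140, 3230 and 4324 with the erythroid, neutrophil and immediate-early covariates, 2766 with the covariate for reads aligned to more than 1 place, 4071 at adjusted p under 0.01 and 4582 at an absolute log2 fold change of at least 1. With an estimated correlation the 25, 24 and 28 called lists became 0. Genes shared by both lymphoma groups went from 1064 to 367 at adjusted p under 0.01, 52 in the earlier runs and 225 with split normal samples.

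In the earlier runs the exact permutation tests gave an adjusted p of 0.2 for kappa share (Myc against vector, -10.45), switched share (54.14 for vector and 37.65 for Myc against normal) and lambda share (vector against normal, -8.43). Those of vector against normal could not pass, since 2 against 3 samples allow no p under 0.1. Leaving out single replicates, heavy chain V share ran from -10.13 to -0.63 for Myc against vector, from 6.4 to 15.9 for vector against normal and from 3.52 to 7.1 for Myc against normal, kappa share ran from -20.77 to -13.01 for Myc against vector and from 18.63 to 26.39 for vector against normal, switched share from -22.41 to -12.52 for Myc against vector and from 33.55 to 43.43 for Myc against normal, and lambda share from -6.09 to -3.71 for Myc against normal. The correlation in vector lymphomas was -0.32 without the 2 farthest samples, -0.10 and -0.06 without replicates 5 and 7, and ran from -0.10 to 0.58; in Myc lymphomas it ran from -0.69 to -0.07. Mitochondrially encoded genes reversed for vector against normal in the earlier runs (0.63), and Bcl2l1 for Myc against normal with the erythroid covariate (-0.94). Kept within 1.5 times the reported counts were those with RLE (8711, 1946 and 7081) and upper-quartile factors (8778, 1965 and 7073), without immunoglobulin genes (8633, 1906 and 6929), without the low-count filter (9098, 1717 and 6889) and by DESeq2 (9349, 2751 and 7970). The share of called genes that rose was 54.2 to 59.2%, 63.1 to 72.0% and 54.5 to 57.0% over the scalings. Named genes kept their call without every single replicate in 61 of 62, 44 of 53 and 56 of 60, and lists in 23 of 25, 22 of 24 and 26 of 28. Depth limits the genes of which a group held 0 to 3 counts, for which no fold change is given.

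With the number in the title as a replicate block, 7352, 1267 and 6149 genes were called. The numbers do not pair the samples: over 24 pairs with the same number the mean correlation of deviations was -0.01 (-0.34 to 0.29), 7 were above 0.1, and 3 of 20 samples correlated best with their own number.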

Other observations

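The heat-shock gene Hspa1a held 663 ± 484 CPM (SD, n = 8) in vector lymphomas, 20.5 ± 4.05 in normal B cells (n = 4) and 2.92 ± 2.20 in Myc lymphomas (n = 8), and Hspa1b followed it (538 ± 421, 17.1 ± 5.18 and 2.75 ± 2.09 CPM). Vector replicate 8, of the earlier runs, held 19.2 CPM of Hspa1a, within the range of the normal samples. Over the earlier runs alone the log2 fold change of Hspa1a went from 5.01 to 2.72 for vector against normal (adjusted p = 0.29, call lost) and from -7.82 to -5.48 for Myc against vector (5.9e-04). Dnajb9, of the unfolded protein response, was 2.21 lower on the log2 scale in Myc than in vector lymphomas, while Asns was highest in Myc lymphomas (105 ± 38.8 CPM, against 33.0 ± 8.1 in vector lymphomas and 2.86 ± 1.35 in normal B cells).

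The prediction for splits of the samples other than the real one was written after the group comparisons had been seen and before any split was run. Over 100 splits per comparison (of 6435, 495 and 495 possible), only the real one called as many genes, and the highest other called 1, 62 and 2273. For the lists 9, 3 and 1 splits called as many as the real one, and the highest other called 27, 26 and 27.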
